A study of Homo sapiens with 9 samples.

How the data were processed

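RNA of 9 colonies of MIA PaCa-2, an established human pancreatic carcinoma cell line, was hybridised to single-colour Agilent whole-genome expression arrays. Per the labels' protocols, cells were irradiated in culture with protons or X-rays, surviving colonies were collected 7 to 17 days later and expanded, RNA was prepared with a spin column kit, and copied RNA was labelled with Cy3. The source labels give a dose of 8 Gy for every colony, while the titles end in 0 Gy. Groups were taken from the source label, which gave 5 proton colonies and 4 X-ray colonies. Proton colonies carried the numbers 1 to 5 and X-ray colonies the numbers 1, 2, 6 and 9. No unirradiated sample was analysed here, so every value compares both kinds of irradiated colony with each other.

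The deposited scanner files hold one intensity per spot, on a linear scale, made with Feature Extraction 10.5.1.1 per the file headers, which subtract a local background and adjust the signal over the array surface. The array carried 41000 probes outside the controls. The deposited value table holds 6991 probes, 17.1% of these, as log2 values. Set against the scanner files, its values equalled log2 of the background-subtracted signal, floored at 10, plus a constant per array, for 100% of the values with a signal over 50 at a tolerance of 0.001. The constant lay between -0.15 and 0.12. Medians of its columns were 7.49, 7.70, 7.21, 6.92 and 7.33 in proton colonies 1 to 5, and 7.09, 6.83, 7.54 and 7.55 in X-ray colonies 1, 2, 6 and 9. Scale and direction of the table were thus settled and its genes were not centred, while the rule by which its probes were selected stayed unknown. The rule behind the constants stayed unknown too, the column medians still differed after them, and the table served only as an alternative.

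Signals were taken as log2 of the processed intensity minus the array's 75th percentile, so that a value of 0 is the signal at that percentile. Spots flagged as outliers (47 to 105 per array) were left out and spots of one probe were averaged. A probe was kept when it was well above background on at least 4 of the 9 arrays, and each gene name was represented by the probe with the highest mean, which gave 18637 features, called genes below. RefSeq accessions matched 23680 of the probes (57.8%) and 11340 of the tested features to current symbols of GRCh38.p14, which was used for names only. Other features kept the array's name. Probe positions are those of the array files, on hg18.

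Proton and X-ray colonies were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All adjusted p-values of single genes below come from this fit unless another is named. Of 43 gene lists fixed before the data were examined, the 40 with at least 5 tested members were tested with camera at its preset correlation, with an estimated correlation and fry as further tests. Cancer-testis antigens, fibroblast markers and endothelial markers had 2, 3 and 4 tested members and were not tested as lists. Among their members, 0 cancer-testis antigens passed the threshold, 1 fibroblast marker was lower in proton colonies, and 1 endothelial marker was higher and 1 lower. Distances between colonies were root mean square log2 differences over all tested genes, compared by exact permutation over the 126 splits of 9 colonies into 5 and 4. Where a probe was not well above background on any array of a group, its fold is given as a lower bound against the lowest signal well above background on each array.

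Genes were named by a rule fixed before the data were examined: the 12 symbols with the largest change past the threshold in each direction, up to 4 members with the smallest p in each list described, and the 10 symbols with the largest spread within groups. The 15 lists described gene by gene were 8 on radiation response, the cell cycle, antigen presentation and angiogenesis, plus those with at least 3 members past the threshold. That choice of lists was made after the counts were seen. Results of some genes that the rule selects are not reported here.

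The 75th percentile signal lay between 667 and 1185 per array, 58.5% to 64.2% of probes were well above background, no spot was saturated, and replicate spots of a probe differed by a median SD of 0.054 to 0.066 on the log2 scale. The number of arrays limits the precision. Each array lay on its own slide. The arrays were scanned on 6 days, of which only scan 4 held both groups (proton colony 2 and X-ray colony 1). The labels call the samples separate colonies and do not say whether they came from separate irradiated cultures, so p-values measure the spread between these colonies only.

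The fit was tested on simulated data with the means and spreads of the 18637 genes. Values were drawn independently from a normal distribution, with the same spread in both groups. Correlated genes, unequal spreads or a colony apart from its group were not simulated. Of 200 genes changed 2-fold, 47.5% were recovered with 5 false calls. Of 200 changed 4-fold, 92.5% were recovered, and of 200 changed 8-fold, 96.5%, with 7 false calls each. With no change there were 0 calls. Alternatives covered background correction, scaling, the filter on dim probes, probes per gene, the deposited value table, outlier flags, scan day, colony number, the variance model, the test, the distance and each colony left out. Figures were drawn with matplotlib 3.10.9.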

Results

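Gene expression was measured in 5 colonies of MIA PaCa-2 cells that survived proton irradiation and 4 colonies that survived X-ray irradiation, each on 1 array. The comparison asked how colonies grown from survivors of both radiation types differed. Signals are log2 values relative to each array's 75th percentile, given as mean ± SD over colonies. The share of probes well above background was 62.1% ± 2.27 (SD, n = 5) in proton colonies and 59.4% ± 0.983 (SD, n = 4) in X-ray colonies.

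Several genes that were bright in all X-ray colonies were not well above background in proton colonies. GSTM3, a glutathione S-transferase (hg18 chromosome 1, probe at 110081137 to 110081196), was not well above background in any proton colony and lay at 4.75 ± 0.23 in X-ray colonies, at least 1247-fold higher (adjusted p = 1.793e-09). A second GSTM3 probe had a log2 difference of -10.15, with 0 proton and 4 X-ray colonies above background, and another was not well above background in any colony. VEGFC, a growth factor for lymphatic vessels, was likewise not well above background in the 5 proton colonies and lay at 3.68 ± 0.26 in X-ray colonies, at least 594-fold higher (adjusted p = 1.677e-07). CASP1, the protease that matures interleukin-1 beta, was at least 34.2-fold lower in proton colonies. Genes of the HOXB cluster of transcription factors on chromosome 17 were lower together: HOXB9 fell from 4.48 ± 0.35 in X-ray colonies to -3.43 ± 0.97 in proton colonies, HOXB8 was at least 94.1-fold lower, and HOXB6 and HOXB5 had log2 differences of -9.29 and -7.94, with 2 and 1 of the proton colonies above background. A second HOXB6 probe gave -4.59. ANKRD22 had a difference of -7.11, with 1 proton colony above background.

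In the other direction, CALB2, the calcium-binding protein calretinin, lay at 4.51 ± 0.42 in proton colonies and -1.06 ± 0.997 in X-ray colonies (47.6-fold, adjusted p = 2.938e-05). OXTR, the oxytocin receptor, was 27.1-fold higher in proton colonies (adjusted p = 0.000223), a log2 difference of 4.76, and its second probe gave 3.05. COXFA4L3, PTPRZ1, B3GAT1, ARAP3, ANO1 and KCNMA1 had log2 differences of 6.42, 5.43, 5.31, 5.29, 5.13 and 4.95, with all proton colonies and 1 X-ray colony, number 6, above background. Of 4 KCNMA1 probes the smallest difference was 0.40.

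**Figure D1:**
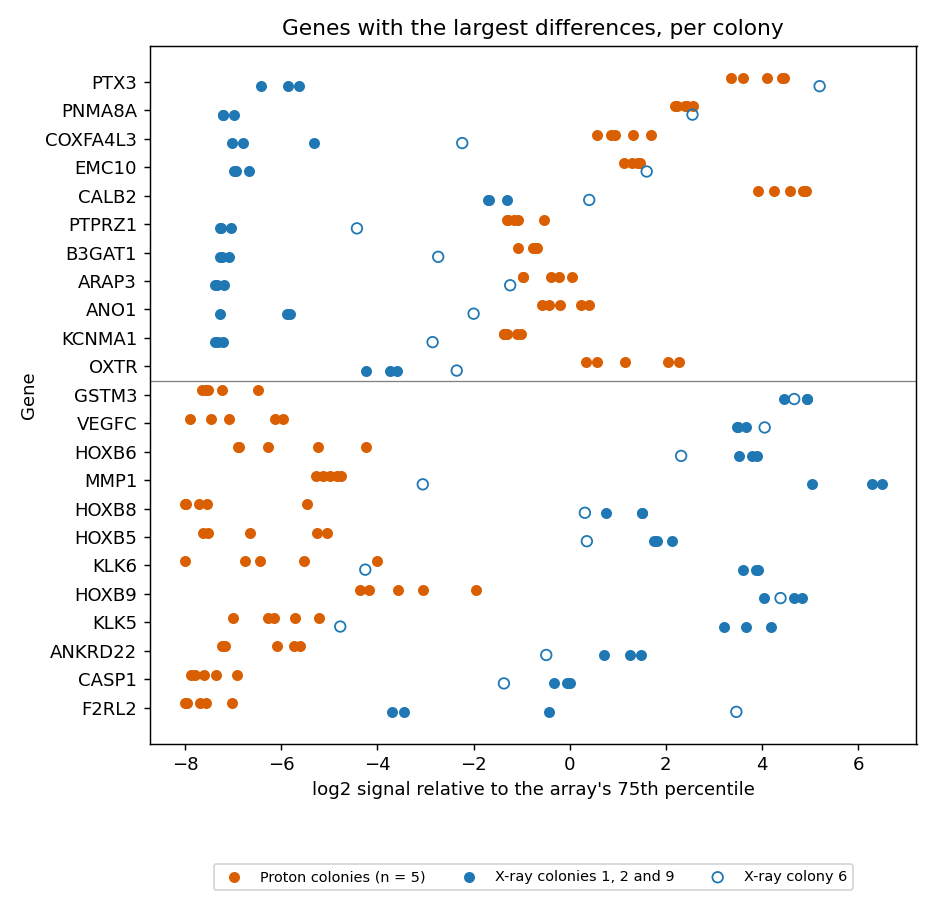
Signal of genes with the largest differences in each direction, as log2 relative to the array's 75th percentile (horizontal axis), 1 point per colony (orange, 5 proton colonies; filled blue, X-ray colonies 1, 2 and 9; open blue, X-ray colony 6). For GSTM3 all 4 X-ray colonies lay together near 4.75, while for PTX3 and PNMA8A X-ray colony 6 lay with the proton colonies.

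Several of the largest differences were not shared by all X-ray colonies. PTX3, a secreted pattern recognition protein, was at 3.99 ± 0.49 in proton colonies, not well above background in those 3 X-ray colonies, and at 5.20 in X-ray colony 6. PNMA8A and EMC10 behaved alike, with 2.56 and 1.60 in X-ray colony 6. Other PNMA8A probes gave differences of 2.68 and -0.22, so its value depends on the probe. The collagenase MMP1 was at 6.29, 6.49 and 5.04 in X-ray colonies 1, 2 and 9, at -3.06 in X-ray colony 6 and at -5.01 ± 0.21 in proton colonies. The kallikrein proteases KLK5, KLK6 and KLK8 showed the same order by proton means, with -4.77, -4.25 and -3.58 in X-ray colony 6. Their proton means were -6.08, -6.15 and -4.17, with 1, 2 and 3 proton colonies well above background. Proton colony 1 lay above X-ray colony 6 for KLK6 (-4.01) and KLK8 (-2.58). F2RL2, a thrombin receptor family member, was at least 22.7-fold lower in proton colonies and brightest in X-ray colony 6, at 3.47. Another F2RL2 probe was above background in 1 X-ray colony and in 0 proton colonies. The bound was 8.04-fold without X-ray colony 6, 42.1-fold without X-ray colony 1 and 39.7-fold without X-ray colony 9. PDZK1IP1, DLC1 and TNFSF4 were not well above background in X-ray colony 6 alone, and their log2 differences between the groups of -2.12, -3.55 and -1.42 did not pass the threshold (adjusted p = 0.4274, 0.1685 and 0.5729).

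Over all genes, 2413 of 18637 (12.9%) passed the threshold, 1232 higher and 1181 lower in proton colonies. At least 2-fold differences numbered 1013, with 531 higher and 482 lower, and 145 were at least 8-fold. Values of both groups did not overlap for 2008 of the called genes. Over all tested genes 14.97% did not overlap, against 1.59% by chance. Leaving out X-ray colony 6 raised the count to 4669. Leaving out any other colony lowered it, to 1801, 2054, 1532, 1801 and 1572 without proton colonies 1 to 5. Without X-ray colony 1, 2 or 9 it was 1419, 1563 and 1439. With scan day as a block, where the contrast rests on 1 proton and 1 X-ray colony scanned together, 527 genes passed, 347 of them among the 2413. An exact permutation test per gene called 0, since its smallest possible p of 0.00794 adjusted to 0.0697 at the lowest, with 4912 genes at an unadjusted p under 0.05. When proton colony 2 and X-ray colony 1, scanned on one day, were left out, 939 genes passed, and these 2 colonies differed in the called direction for 94.99% of them. A normexp background correction called 191 genes, and 2087 with high local backgrounds capped. Extreme local backgrounds lay mostly on the arrays of proton colonies 3 and 4, with 10 and 5 spots. Array quality weights, which gave X-ray colony 6 a weight of 0.182, called 6429.

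Genes of antigen presentation were lower in proton colonies. Of 17 tested members 0 were higher and 7 lower past the threshold over all genes, and 9 were lower when adjusted over the list alone. The median log2 difference was -0.40 (camera adjusted p = 0.007212). Fry called the list too (adjusted p = 0.007545). With an estimated correlation camera did not call it (adjusted p = 0.9053). Its unadjusted p there was 0.04435, the only one of all lists under 0.05. The immunoproteasome subunit PSMB8 fell by 1.55 ± 0.19 (SE) on the log2 scale (adjusted p = 0.0007952), the class I molecules HLA-B and HLA-C by 0.84 ± 0.16 and 0.68 ± 0.13 (SE), and the peptide transporter TAP1 by 0.62 ± 0.13 (SE). PSMB8, PSMB9 and TAP1 neighbour each other on chromosome 6. The call was also lost without a filter on dim probes (median -0.42, adjusted p = 0.06637) and with scan day as a block (median -0.27, adjusted p = 0.2326). Over the alternatives that tested this list with the preset correlation, its adjusted p lay between 3.352e-05 and 0.2326. In the pair scanned on one day, 15 of the 17 members were lower in the proton colony. Other lists leaned as far in that pair, such as G2/M and mitosis with 20 of 22 lower. Some leaned the other way, such as interferon-stimulated genes with 1 of 17 lower. This pair therefore does not set antigen presentation apart.

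**Figure D2:**
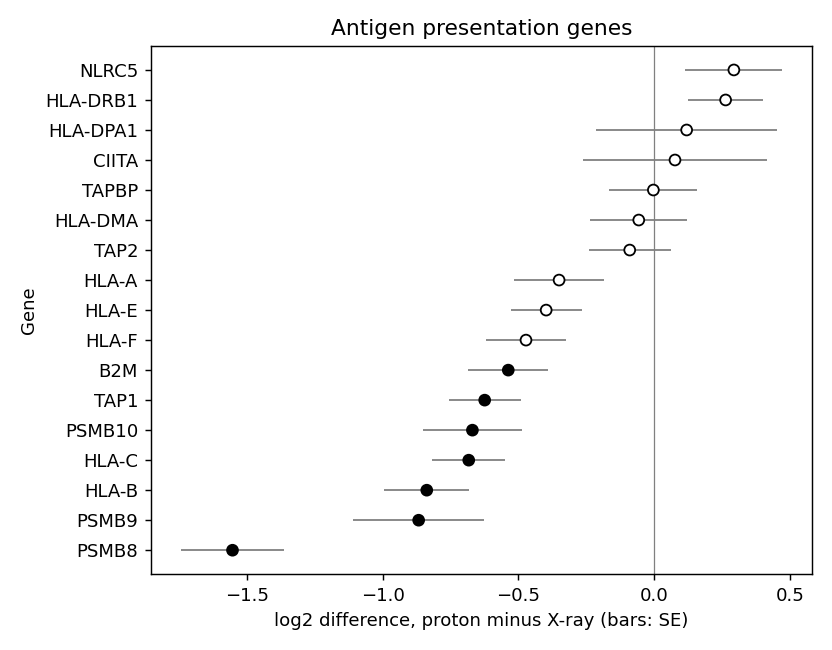
Log2 difference of each tested antigen presentation gene, proton minus X-ray colonies (horizontal axis; bars, SE; filled points, past the threshold). The 7 filled points, from B2M to PSMB8, lie below 0.

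Of 14 angiogenesis factors, VEGFC and FGF2 were lower in proton colonies, FGF2 by 2.37-fold (adjusted p = 0.003882), while TYMP and PGF, at log2 differences of -0.40 and -0.57, did not pass (adjusted p = 0.1481 and 0.288). Camera did not call this list (adjusted p = 0.2) and fry did (adjusted p = 0.007545). The list's median log2 difference was -0.24 and its mean -1.02, a mean to which VEGFC alone brings a difference of -10.6. No list but antigen presentation passed camera, and 3 had an unadjusted p under 0.05.

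Except where stated, the counts given are the same when adjusted over the list alone. Among 19 p53 target genes only FAS, a death receptor, passed, 3.04-fold lower in proton colonies (adjusted p = 0.007828). The cyclin-dependent kinase inhibitor CDKN1A differed by -0.72 ± 0.32 (SE) and did not pass (adjusted p = 0.1642), nor did XPC (-0.51) or TIGAR (0.36). Among 20 homologous recombination genes, FANCI, BARD1 and RAD54L were lower, by 1.80-, 1.79- and 2.11-fold, and RAD51D was 2.03-fold higher. FANCI probes gave differences from -0.13 to -0.85. Among 13 end joining genes, XRCC5, which encodes the Ku80 subunit, was 1.76-fold lower and the polymerase POLL 1.53-fold higher, while PRKDC (-0.37) and XRCC4 (-0.50) did not pass. Of 16 checkpoint genes 0 passed in limma and 4 had an unadjusted p under 0.05. These were CLSPN (log2 difference -0.60, adjusted p = 0.05063), CDC25C (0.59), H2AX (0.38) and CHEK1 (0.34).

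Of 20 S phase genes, RRM2, a ribonucleotide reductase subunit, POLA1 and TYMS were lower in proton colonies, by 2.11-, 1.83- and 1.40-fold, and PCNA (-0.36) did not pass. Of 22 genes of G2/M and mitosis, 0 passed in limma and 3 had an unadjusted p under 0.05. CENPA, BUB1, CDK1 and TOP2A had log2 differences of -0.57, -0.39, 0.33 and -0.71 and adjusted p-values of 0.1006, 0.1549, 0.1611 and 0.191. The list mean was 1.32 in X-ray colony 6 and 2.27, 2.20 and 2.44 in X-ray colonies 1, 2 and 9, against 1.58 to 2.07 in proton colonies. Camera called this list lower in proton colonies when X-ray colony 6 was left out (median -0.52, adjusted p = 0.0002001), and with the preset correlation its adjusted p lay between 3.415e-05 and 0.7515 over the alternatives. With an estimated correlation, run on all 9 colonies, the list was not called (adjusted p = 0.9053). Among 10 cell cycle inhibitors and senescence genes, CDKN1C and CDKN1B were 3.65- and 2.76-fold higher in proton colonies and RB1 was 1.40-fold lower. This list had a median of -0.022 and a mean of 0.26.

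Lists of metabolism, drug transport and matrix held changes in both directions. Of 16 hypoxia response genes, MXI1 and NDRG1 were 4.67- and 3.33-fold higher in proton colonies, and P4HA2 and LDHA were 1.54- and 1.52-fold lower. Adjusted over the list alone, 4 were higher and 3 lower, and the list's median was -0.26 and its mean 0.19. Of 20 glycolysis genes, the lactate transporter SLC16A3 and PFKFB3 were 2.75- and 1.92-fold higher, LDHA was lower, and HK2 (-0.59) did not pass. The list's median was -0.012 and its mean 0.065. One PFKFB3 probe went the other way (-1.15), and a second SLC16A3 probe gave a log2 difference of 0.74 against 1.46. Of 18 NRF2 targets, FTL and TALDO1 were 1.77- and 1.64-fold higher, and GCLM and ABCC2 were 1.57- and 1.56-fold lower, and adjusted over the list alone 4 were higher and 2 lower. Of 22 genes of cholesterol and fatty acid synthesis, DHCR7 was 1.56-fold higher, INSIG1 was 1.64-fold lower and IDI1 (0.65) did not pass. Of 14 genes of drug efflux and gemcitabine metabolism, 4 were lower, among them ABCC3 by 3.27-fold, and ABCC5 was 1.48-fold higher. Adjusted over the list alone, 3 were higher and 4 lower. Of 14 collagens and matrix genes, LAMB3 and COL4A2 were among the 3 higher, by 5.03- and 1.80-fold, and COL1A2 and COL7A1 were 3.08- and 1.74-fold lower. Adjusted over the list alone, 4 were higher and 2 lower. With the normexp correction COL7A1 turned to 0.47.

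On average, colonies of one radiation type resembled each other more than colonies of the other type, with the exception of X-ray colony 6, which lay closer to every proton colony than to the other X-ray colonies. The mean distance was 0.891 between and 0.570 within groups, a difference of 0.320 (exact permutation test, one-sided, p = 0.00794, the smallest that the number of colonies allows). With the normexp correction it was 0.154 and did not pass (exact permutation test, p = 0.175). Proton colonies lay 0.356 to 0.584 apart. X-ray colonies 1, 2 and 9 lay 0.411 to 0.488 apart, and X-ray colony 6 was 0.930 to 0.947 from them and 0.836 to 0.872 from proton colonies. The proton and X-ray colony scanned on one day were 0.902 apart. The mean distance was 0.499 among proton colonies and 0.689 among X-ray colonies, a difference of -0.190 that did not pass (exact permutation test, two-sided, p = 0.0556). Without X-ray colony 6 it turned to 0.060 (exact permutation test, p = 0.554), and with the normexp correction to 0.466 (exact permutation test, p = 0.230).

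**Figure D3:**
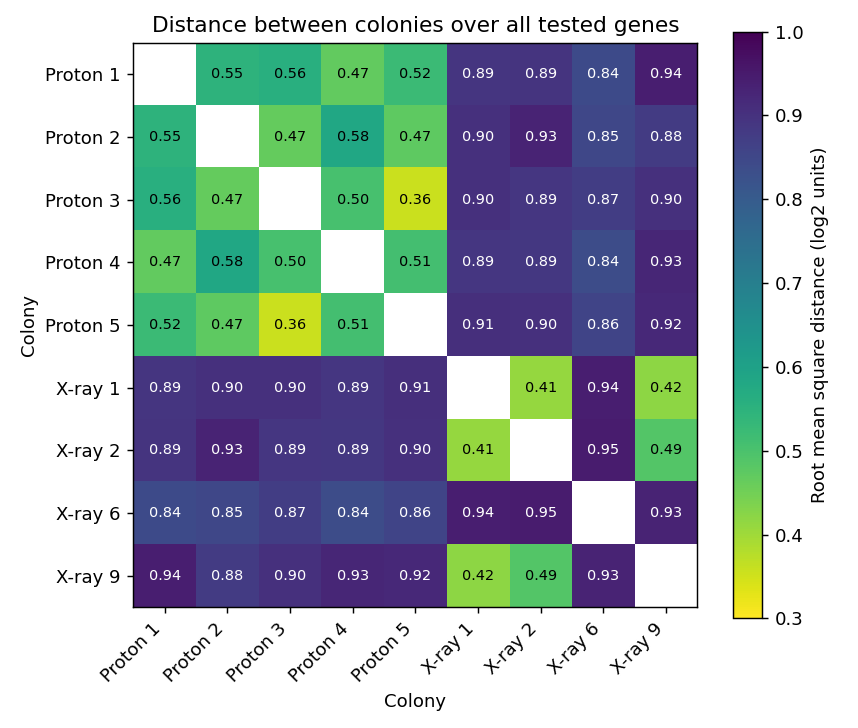
Root mean square log2 distance between each pair of colonies over all tested genes (colour and number in each cell; both axes list the 9 colonies). Proton colonies are at most 0.584 apart and X-ray colony 6 is at least 0.836 from every other colony.

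Along whole chromosomes, genes of chromosome 10 lay above the median difference in 362 of 419 cases and genes of chromosome 14 in 64 of 369. The comparison by chromosome was added after the data were examined.

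**Figure D4:**
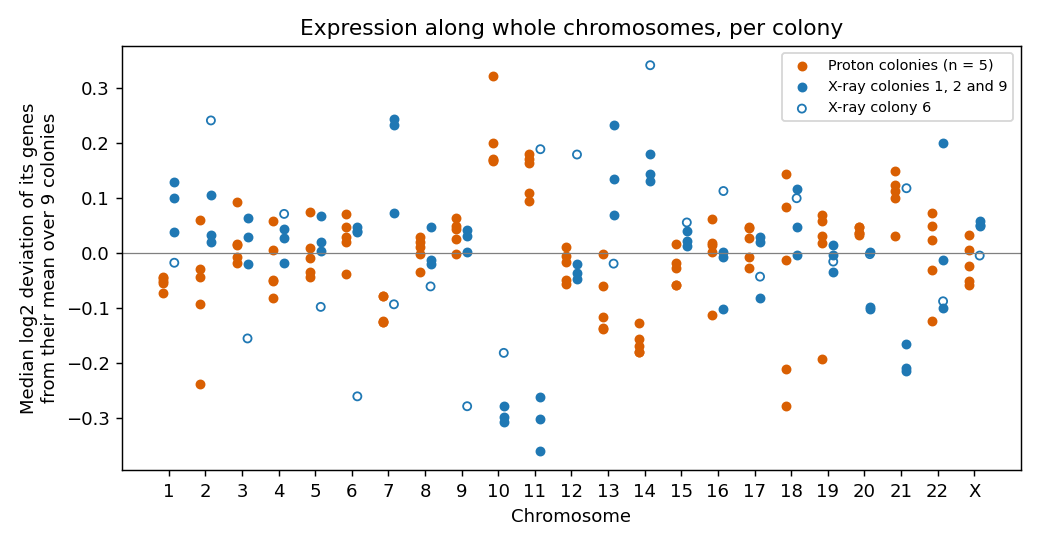
Median log2 deviation of the genes of each chromosome from their mean over the 9 colonies, relative to the array's median over all genes (vertical axis), by chromosome (horizontal axis), 1 point per colony (orange, 5 proton colonies; filled blue, X-ray colonies 1, 2 and 9; open blue, X-ray colony 6). On chromosome 10 every proton colony lies above every X-ray colony, and on chromosome 14 below. By smaller margins, they also lie above on chromosome 20 and below on chromosome 1.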

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

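Tests of scan day, of whole chromosomes and of the origin of X-ray colony 6 were chosen after the results they bear on had been seen. Excess neighbouring calls were noticed from the HOXB and GSTM genes before they were counted.

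Among 178 groups of values tested for a colony far from the others of its group, 27 stood out, of which 19 were due to X-ray colony 6. Chance gives about 1 in 20, but 10 of the genes were named for their spread within groups, so this count cannot be set against that rate. The gap to the nearest other colony, as a share of the group's range, was 0.932 for PTX3, 0.975 for PNMA8A, 0.964 for EMC10, 0.917 for PTPRZ1, 0.959 for B3GAT1, 0.968 for ARAP3, 0.963 for KCNMA1, 0.848 for MMP1, 0.962 for KLK6, 0.89 for KLK5, 0.929 for KLK8, 0.907 for RAD54L, 0.88 for POLA1, 0.901 for PGF, 0.957 for TALDO1, 0.927 for COL4A2, 0.951 for PDZK1IP1, 0.926 for DLC1 and 0.847 for TNFSF4, all in X-ray colony 6. X-ray colony 1 stood apart for CLSPN (0.83). Proton colony 1 stood apart for PTPRZ1 (0.711), proton colony 2 for B3GAT1 (0.799) and TYMP (0.8285), proton colony 3 for CDKN1C (0.828), and proton colony 4 for HOXB8 (0.822), FANCI (0.8) and RAD54L (0.799). Over all tested genes, X-ray colony 6 stood apart for 7.10%, against at most 2.02% for any other colony.

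X-ray colony 6 lay further from X-ray colonies 1, 2 and 9 (0.930 to 0.947) than from proton colonies (0.836 to 0.872), while the other pairs of one group scanned on different days lay 0.356 to 0.584 apart. A proton colony like the sampled ones under a wrong label is argued against by genes not well above background in one set and bright in the other. Bright meant at least 4-fold above the lowest signal well above background, while colony 6 was judged only by being well above background or not. Of these genes, 25.6% went with the X-ray colonies in colony 6: 18 of 39 bright in X-ray colonies 1, 2 and 9, GSTM3 and VEGFC among them, and 4 of 47 bright in proton colonies. With colony 6 held to 4-fold too, 11 genes were bright in all 4 X-ray colonies alone and 4 in the 5 proton colonies alone. By the same rule, 39 were bright in the proton colonies and colony 6, and 21 in X-ray colonies 1, 2 and 9 alone. A proton colony unlike the sampled ones was not tested, so a label error of that kind stays open. A mixture of both kinds of cells is argued against by 8 genes that were at least 16-fold above the lowest signal well above background in colony 6 and not well above background elsewhere, such as A2M, LRRN3 and HOXC9, chosen after their values were seen, against at most 1 in any other colony (34 against at most 29 at 4-fold). Cells of a line that expresses MTAP, CDKN2B, CDH1 or EPCAM are argued against, since 0 of 7 probes were above background in colony 6, as in the other 8 colonies, which leaves open lines that also lack these genes. A separate origin of colony 6 among the irradiated cells may explain its profile and was not tested. X-ray colony 6 was also the only array of scan 6, as proton colonies 1 and 5 were of scans 3 and 1. An effect of its scan day or slide therefore cannot be told apart from the colony.

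The genes past the threshold may reflect radiation type or differences between the founding cells of the colonies, which the design does not separate. Only 1 of 100 splits of the colonies, the real one, called 2413 genes or more, and the highest other split called 8. This argues against a random grouping of independent colonies. The splits cannot tell radiation type from founders shared within a group. Of the 939 genes called without proton colony 2 and X-ray colony 1, which shared a scan day, 94.99% differed in the called direction between these colonies, against at most 79.9% for pairs of one group left out alike, which argues against scan day as the whole source on the evidence of 1 pair, and 527 genes passed with scan day as a block. Scaling and detection are argued against by the setting that moved the count most among them, without a filter on dim probes, which left 1681 genes. Colonies of one group that share a founder would make these counts too high, and the data do not say whether they do.

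Neighbouring genes were called in the same direction more often than chance order allows. There were 386 such pairs within 100 kb, against at most 140 in 1000 reassignments, and 154 against at most 94 among RefSeq mRNAs whose symbols have different stems, which argues against genes of one name series as the whole source, while sequence similarity was not compared. A test of large chromosome blocks, set before its result was seen, found 0 of 379 windows of 5 Mb beyond the largest reassignment (0.89), so shifts of that size over such windows are argued against. That bound exceeds the 0.58 that 1 more copy beside a pair would give, and a second test, chosen after this result, asked about whole chromosomes. There 12 of 23 chromosomes had more genes on one side of the median difference than in any reassignment. Genes were reassigned singly, as if neighbours were independent, which the pairs above argue against, so this number may be too high. Some of the shifts rested on 1 or 2 colonies (chromosome 6 turned to -0.0077 without X-ray colony 6). For chromosomes 10 and 14 a candidate explanation is a difference in chromosome number, which these arrays did not measure.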

How the results depend on the processing

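The capped background and the scanner values on the value table's probes were chosen after seeing the data. The planned normexp correction gave 191 genes, 10 lists, a separation of 0.154 and a spread difference of 0.466, and moved the median difference of all genes from 0.048 to 0.214. Proton colonies 3 and 4 had 10 and 5 spots with local backgrounds above 1000, up to 54067, against array medians of 55 and 52. With the local backgrounds of every array capped at their 99th percentile, the correction gave 2087 genes, 1907 of them among the 2413, 1 list, 0.209 and -0.118. Capping high backgrounds thus undid most of the change. The cap also moved the 5th percentile of proton colony 5, from -2.99 to -3.34, and the named spots were not tested alone. Counts of genes were 728 in the value table and 1178 with scanner values on its 3877 features, where fewer genes were tested, 527 with scan day as a block, 6429 with array quality weights, in which X-ray colony 6 weighed 0.182, 1013 at 2-fold or more and 0 by permutation. Lists called numbered 0 without a filter on dim probes, 0 in the value table and 0 with scanner values on its probes, where 26 lists were tested and antigen presentation was not among them, 0 with an estimated correlation, 2 with fry and 2 with scan day as a block. The spread difference passed the threshold with every probe (-0.190), in the value table (-0.377), with scanner values on its probes (-0.386) and with correlation distance (-0.0151). Apart from the causes stated, the cause was not tested. In all other settings the separation kept its direction and stayed past the threshold, from 0.0236 with correlation distance to 0.637 with scanner values on the value table's probes. The value table's median difference of all genes was 0.178, that without a filter -0.11 and that with scan day as a block -0.064.

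Leaving out 1 colony gave 1419 to 4669 genes, 1 to 6 lists, separations of 0.284 to 0.419 and spread differences of -0.290 to 0.060. The lowest gene count came without X-ray colony 1. The highest gene count and the only turned spread came without X-ray colony 6, and 6 lists passed then. Lists numbered 2 without proton colony 1. The spread difference passed the threshold without any 1 of proton colonies 1 to 5, at -0.207, -0.203, -0.172, -0.202 and -0.168.

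Colony numbers 1 and 2 occur in both groups, but nothing says that they pair colonies, and deviations of same-numbered colonies correlated at 0.069 and -0.205. With the number as a replicate block, the contrast rests on colonies 1 and 2 of each group, with 1 residual degree of freedom. In that fit 1681 genes and 6 lists passed. A slide block was not run, because each array was on its own slide.

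Among named genes, PNMA8A turned to -0.22 with probes above background on all arrays, where another probe stands for it. H2AX turned to -0.014, PGF to 0.26 and COL7A1 to 0.47 with the planned normexp and kept their direction with capped backgrounds, where COL7A1 (-0.46) did not pass the threshold. XRCC4 turned to 0.58 with scan day as a block, and the cause was not tested. Over all named genes and settings chosen beforehand, these 5 turned and 1454 values kept direction and side of the threshold. Another 41 gained the threshold and 291 lost it, 62 of them in the exact permutation, whose lowest adjusted p was 0.0697. Signals near background limit the lower end of folds.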

Other observations

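The test by chromosome was chosen after the results were seen. Interferon-stimulated genes varied more between X-ray colonies than between radiation types. Their mean was 1.11 in X-ray colony 6 and -2.23, -2.05 and -1.44 in X-ray colonies 1, 2 and 9, against -0.97 to -0.079 in proton colonies. Of 17 members 0 passed the threshold in limma and 7 had an unadjusted p under 0.05. Camera with its preset correlation called the list higher in proton colonies when X-ray colony 6 was left out (median 1.43, adjusted p = 0.002633). It also did so with a block for scan day or colony number (medians 2.10 and 1.46), and in no other setting. X-ray colony 6 was alone in its scan and number, so each block also takes it out of the contrast. These settings are therefore not independent for this list. Over the alternatives with the preset correlation its adjusted p lay between 4.155e-08 and 0.8826, and with an estimated correlation, run on all 9 colonies, the list was not called (adjusted p = 0.9053).

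Genes of chromosome 10 were higher in proton colonies as a whole: 86.4% of 419 lay above the median difference of all genes, with a median excess of 0.43 (0.44 with quantile scaling, 0.36 with capped normexp, 0.47 without X-ray colony 6). On chromosome 14 the share was 17.3% of 369, with a median of -0.40 (-0.39 with quantile scaling, -0.35 with capped normexp, -0.33 without X-ray colony 6). By their medians over the chromosome, all X-ray colonies, number 6 included, lay on one side of the proton colonies on both chromosomes. They did so on chromosomes 1 and 20 too, where the median shifts were smaller, at -0.12 and 0.10. On chromosome 11, 81.1% of 688 genes lay above the median, with X-ray colonies 1, 2 and 9 at -0.30, -0.26 and -0.36 and X-ray colony 6 at 0.19, beside proton colonies at 0.095 to 0.180. Of the 12 of 23 chromosomes shifted beyond any reassignment, not all held across colonies. Chromosome 6 turned from 0.089 to -0.0077 and chromosome 9 fell from 0.070 to 0.015 without X-ray colony 6. On chromosome 18 proton colonies 3 and 4 lay at -0.28 and -0.21 and proton colonies 1 and 2 at 0.084 and 0.14. The shifts of chromosomes 10 and 14 may reflect colonies that differ in chromosome number, a hypothesis formed on these same data and not tested. DNA copy number was not measured here, and shared regulation of neighbouring genes was not tested as a source.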
